A study of Homo sapiens with 59 samples.

How the data were processed

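RNA from 3 bladder cancer cell lines was extracted as total RNA with a miRNeasy kit and made into libraries with a TruSeq stranded mRNA kit, per the labels' protocols, and sequenced on an Illumina HiSeq 2000, per the series' design text. Each of the 59 samples is 1 sequencing run of a library, and its title carries the target, cell line, time, treatment arm (HOX siRNA or negative control siRNA), a replicate number and a run letter. Runs with the same replicate number were summed, which gave 32 libraries in 12 groups (8 groups of 3 libraries and 4 of 2), where the design text speaks of triplicates. The replicate number was taken from the title. The separate replicate entry of the labels differs from it in 3 control groups (UMUC5 at 48 h, 5637 at 24 h and 5637 at 72 h), and the group of each sample does not depend on either number. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

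The authors' files hold 1 line per transcript with its length, an effective length, TPM and a read number. Expected counts (the read numbers per transcript) were estimated with Salmon, per the file headers and the submitters' processing notes, which also name GRCh37. The Salmon version, index, library type and strand setting are not given in the sources used here. The TPM values in the deposited files are the same estimates divided by effective transcript length and scaled to a fixed total in each file, per the file headers. They were used only for the share of HOX transcripts in control cells, and lengths only as a check. Of all values above 0, 29.2% were not whole numbers (tolerance 0.001), which happens when reads match several transcripts. Each file lists 200249 transcript identifiers with no gene names. They were matched without their version number to GENCODE release 29, the annotation at hand, which is built on GRCh38: 179628 identifiers (89.7%) matched, in 52423 genes, of which 8772 had reads. Coordinates are those of the annotation on GRCh38 and were not converted from the submitters' build. Transcripts without a match (82.37% of reads on the 2 largest and 1.81% on all others) stayed out of library sizes and tests. Estimated counts were summed per gene and library and rounded to whole numbers before testing.

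Depth ranged from 33542 to 119256 reads per library over all transcripts (median 74103.5) and from 6585 to 16246 on annotated genes (median 11173). Runs of 1 library were compared with a chi-square test over genes with an expected count of at least 5. The median ratio of chi-square to its degrees of freedom was 1.232 over 25 pairs of runs of 1 library and 2.943 over 28 pairs of libraries of 1 group, with p under 0.05 for 11 of the 25 run pairs (ratios up to 3.555) and all 28 library pairs. Runs of 1 library were summed as the labels name them, although some thus differed by more than sampling noise, and no library was merged with another. HOXA13 siRNA replicate 2 in UMUC5 at 24 h includes 2 runs with 16 and 45 reads.

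Genes were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F-test, two-sided, with robust estimation, TMM scaling and filterByExpr (minimum count 10, minimum total 15). Each cell line had 1 fit with 1 mean per group over both times and no replicate block, which left 7 residual degrees of freedom in UMUC5 and TCCSUP and 6 in 5637. Contrasts were HOX siRNA minus control at each time, the difference of those effects between times, control cells between times, and the difference of HOXB13 siRNA effects between TCCSUP and 5637 at 72 h in a fit of both lines. Benjamini-Hochberg adjusted p under 0.05 was called. Log2 fold changes use a prior count of 0.125. CPM are counts per 1000000 of the TMM-scaled library size over the genes tested, and RPM are reads per 1000000 reads on annotated genes. DESeq2 1.42.0 was an alternative test without that filter; it gave an adjusted p for 1734 genes in UMUC5, 5330 in 5637 and 6862 in TCCSUP. Where a group had only counts of 0, folds are given as bounds against 3 reads per library. These bounds use the mean RPM of the other group, without TMM scaling and without its spread.

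The 37 gene lists fixed before the data were examined were tested with camera in limma 3.58.1 (preset correlation 0.01), with estimated correlation and with fry, where at least 3 members passed the filter. Only TGF-beta and BMP targets, the type I interferon response and mitochondrially encoded mRNAs reached that number in any comparison. Genes named in the text follow a rule also fixed then. HOXA13 and HOXB13 are given in every library. In siRNA comparisons the 5 highest and 5 lowest log2 fold changes among called genes with at least 5 CPM and no overlap between groups would be named, with the 5 smallest adjusted p in each direction, or, where none was called, the 3 smallest p as values. From a list with a call, or with at least 3 called members, up to 4 members are named. In tests of time, interaction and cell line, the 3 highest and 3 lowest called log2 fold changes are named, and in overlaps up to 5 genes per direction. The comparison of control cells between lines, added later, used the parts of the rule for siRNA comparisons. A gene named outside this rule is said to be.

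The steps were tested on simulated counts drawn from the real libraries' means and sizes, in 10 simulations per comparison with 20 genes changed 2-, 4- or 8-fold in each. In the siRNA comparisons 8-fold changes were recovered for 91.7% and 81.7% of changed genes in UMUC5 at 24 and 48 h (208 genes), 83.3% at both times in 5637 (250 genes), and 81.7% and 85% in TCCSUP at 48 and 72 h (220 genes). Of unchanged genes 0.63% and 0.34% were called in UMUC5, 0.23% and 0.27% in 5637, and 0.27% and 0.37% in TCCSUP, and 0 changed genes were called in the wrong direction.

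Alternatives were RLE scaling, library size only, no filter on low counts, a filter at 1 CPM in 3 libraries, DESeq2, an average transcript length offset, the first run of each library only, a fit of the compared groups only, the replicate number as a block and leaving out each library in turn. Added after the data were seen were tests on genes without a CA or TG run of 20 nt, tests without the 6 libraries with over 2000 genes detected, tests with unmatched transcripts kept, and the comparison of control cells between lines. Runs of CA or TG were searched in GENCODE release 29 transcript sequences, and shares of protein-coding transcripts cover the 125416 whose length equals that in the deposited files. Exon overlaps between genes were found with bedtools 2.31.1, and 1 overlap is not reported here. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.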

Results

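Gene expression was measured by RNA sequencing in 3 established human bladder cancer cell lines, UMUC5, 5637 and TCCSUP, after transfection with small interfering RNA (siRNA), short duplex RNA that directs the degradation of a matching transcript. UMUC5 cells received siRNA against HOXA13 or a negative control siRNA and were collected at 24 and 48 h. 5637 cells received siRNA against HOXB13 or the control siRNA and were collected at 24 and 72 h, and TCCSUP cells received the same pair of treatments and were collected at 48 and 72 h. HOXA13 and HOXB13 are paralogous homeobox transcription factors of the posterior HOX clusters, and the comparisons ask which transcripts differ when either is targeted. The 59 sequencing runs belonged to 32 libraries in 12 groups. Of these groups, 8 held 3 libraries and 4 held 2 libraries, the latter being the UMUC5 controls at 48 h, the 5637 controls at 24 h and at 72 h, and the TCCSUP HOXB13 siRNA group at 72 h.

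The libraries were shallow. The 32 libraries held 2275132 estimated reads in all, from 33542 to 119256 per library (52005 to 117712 in UMUC5, 33542 to 87567 in 5637 and 57693 to 119256 in TCCSUP). Of all reads, 82.37% lay on 2 transcripts without a gene in the annotation used, 1 of 5070 nt with 1627192 reads and 1 of 1869 nt with 246882 reads. RefSeq 18S ribosomal RNA genes are 1869 nt long and RefSeq 28S genes 5054 to 5077 nt, a match of length only. Reads on annotated genes made up 15.82% of the total, 359813 reads, from 6585 to 16246 per library (6585 to 12081 in UMUC5, 8871 to 16246 in 5637 and 10563 to 13673 in TCCSUP). Between 649 and 3087 genes per library had at least 1 read, and between 127 and 246 genes had at least 10 reads. A count of 0 in 1 library allowed up to 3 reads, which was 185 to 456 reads per 1000000 reads on annotated genes (RPM), depending on the library. Intervals and floors here cover counting error only, because reads without molecular identifiers can be copies of 1 molecule.

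**Figure D1:**
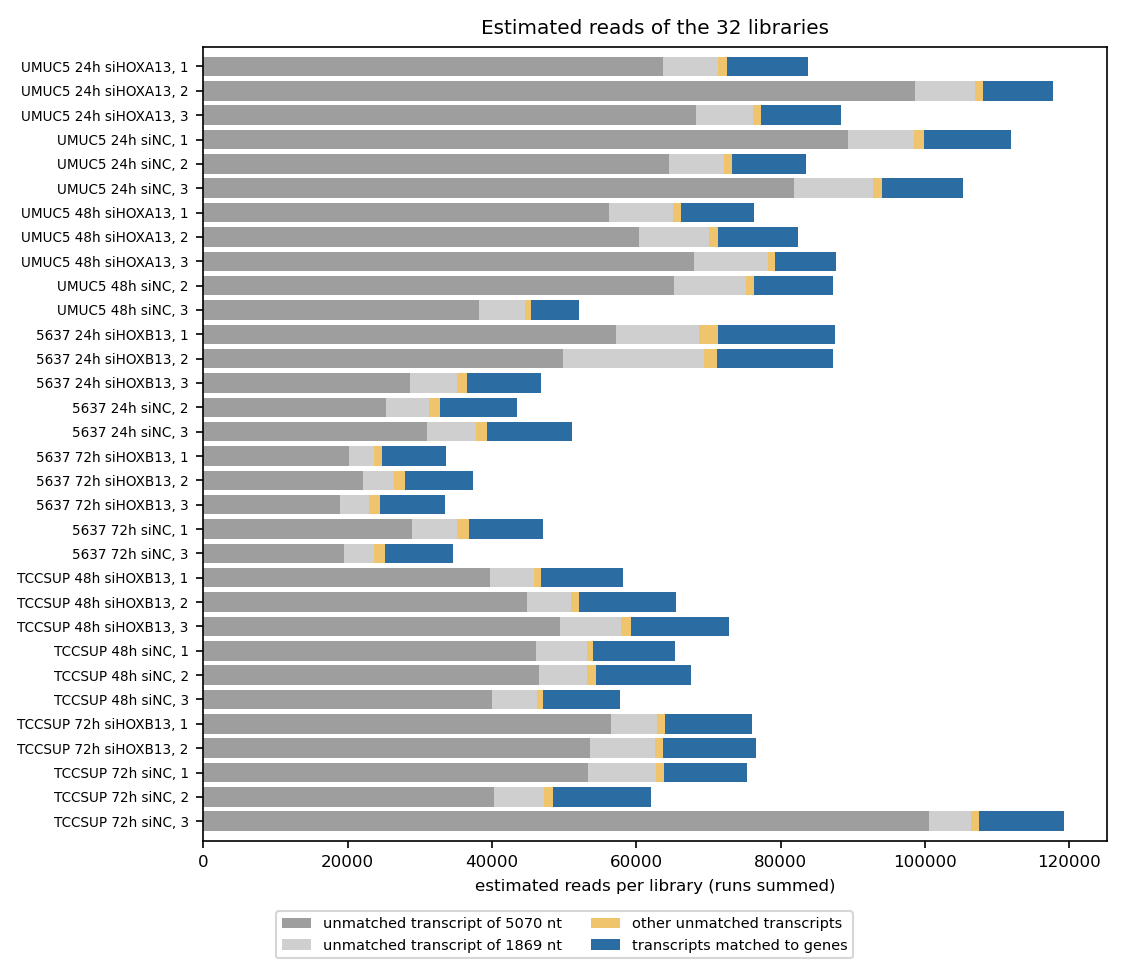
Estimated reads of each of the 32 libraries, with sequencing runs summed, on the x axis; colours divide each bar into the unmatched 5070 nt and 1869 nt transcripts, other unmatched transcripts and transcripts matched to annotated genes. The 2 named unmatched transcripts took 82.37% of all reads, and the part matched to genes ranged from 6585 to 16246 reads per library.

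The genes with the most reads over all libraries were RAB7A, a small GTPase of late endosomes, with 19057 reads (5.30% of reads on annotated genes), the cytoskeletal actin ACTB with 18418 (5.12%), the glutamine transporter SLC1A5 with 15025 (4.18%), the death receptor family member TNFRSF21 with 13837 (3.85%), the epithelial 14-3-3 protein SFN with 7806 (2.17%) and the carboxypeptidase CPA4 with 7397 (2.06%). Several transcripts that epithelial cell lines usually hold at high levels had few reads over the 32 libraries: GAPDH had 85.7, EEF1A1 118, KRT8 15, KRT18 25 and KRT5 17. The mesenchymal gene VIM had 1. Together, 42 ribosomal protein genes held 843.7 reads. Protein-coding transcripts with an uninterrupted CA or TG dinucleotide run of at least 30 nt were 0.538% of protein-coding transcripts and held 56.76% of their reads. Among the genes tested between groups, those with such a run of at least 20 nt made up 64.9% in UMUC5, 64.8% in 5637 and 63.2% in TCCSUP. RAC1, SET, ESCO2, BUB1B-PAK6, FST, IFI44L and the mitochondrial genes among the genes named for the siRNA comparisons had no such run, and the other genes named for them had 1 of 23 to 48 nt. Read numbers in these libraries therefore cannot be set against usual expression levels of different genes, and the tests are between groups for the same gene.

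**Figure D2:**
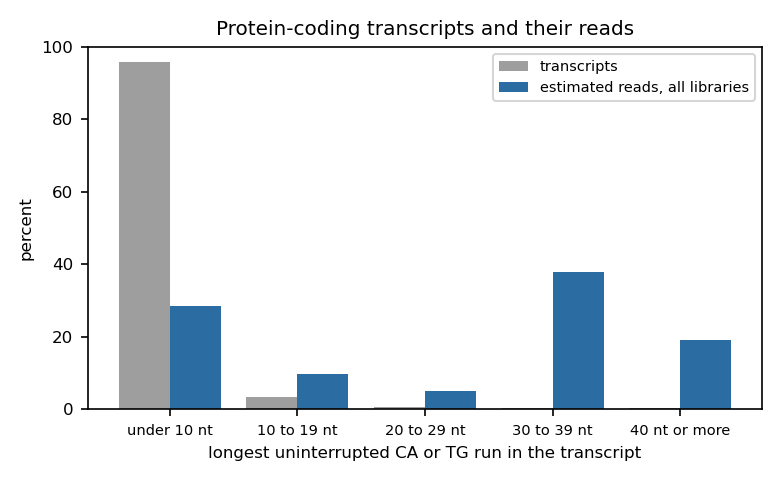
Percent of protein-coding transcripts (grey) and percent of their estimated reads over all libraries (blue) on the y axis, by the length of the longest uninterrupted CA or TG run in the transcript on the x axis. Transcripts with a run of at least 30 nt, the 2 right-hand classes together, were 0.538% of transcripts and held 56.76% of reads.

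Neither siRNA target could be followed at this depth. HOXA13 (ENSG00000106031, GRCh38 chromosome 7, 27193503 to 27200106, minus strand, its exons overlapping those of HOTTIP on the opposite strand) had 0 reads in each of the 32 libraries. HOXB13 (ENSG00000159184, GRCh38 chromosome 17, 48724763 to 48729178, minus strand) had 14 reads in all. In 5637 the libraries labelled HOXB13 siRNA held 3, 0 and 0 HOXB13 reads at 24 h and 4, 2 and 1 at 72 h, and the 4 control libraries held 0. The group sums were 3 reads at 24 h (exact Poisson 95% interval 0.619 to 8.77) and 7 at 72 h (2.81 to 14.4), against control sums of 0 (upper limit 3.69 at each time). The direction in 5637 thus runs against the labels, and the difference over the 6 siRNA and 4 control libraries had p = 0.133 in an exact two-sided permutation test of RPM. With reads in only 4 libraries, all labelled HOXB13 siRNA, that test could not have given p under 0.05. In TCCSUP the libraries labelled HOXB13 siRNA held 0, 0 and 1 HOXB13 reads at 48 h and 0 and 1 at 72 h, the controls held 0, 0 and 0 at 48 h and 0, 0 and 1 at 72 h, and 1 UMUC5 library, labelled HOXA13 siRNA replicate 1 at 24 h, held 1. Whether either target was lowered cannot be read from these counts, so each comparison that follows is between libraries as labelled.

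In UMUC5, the transcripts closest to a difference after HOXA13 siRNA were seen at 48 h. STAT5B, a transcription factor downstream of cytokine receptors (chromosome 17, 42199168 to 42276707), stood at 4959 ± 275 scaled counts per 1000000 (CPM) in the 3 libraries labelled HOXA13 siRNA and at 2726 ± 179 (SD) in the 2 controls, a log2 difference of 0.85 ± 0.27 (SE) with all 3 siRNA libraries above both controls (adjusted p = 0.728, edgeR). SFN (chromosome 1, 26863138 to 26864457) stood at 44771 ± 4504 and 28802 ± 3508 CPM, a log2 difference of 0.63 ± 0.20 (adjusted p = 0.728), and radixin, RDX, which links actin to the membrane, differed by 0.53 ± 0.21 (adjusted p = 0.998). At 24 h the 3 smallest p values belonged to the zinc finger gene ZNF134 with a log2 difference of -0.93 ± 0.49, the interferon-induced 2'-5'-oligoadenylate synthetase OAS3 with -0.43 ± 0.22 and RAC1, which regulates actin at the cell edge, with 0.36 ± 0.19 (adjusted p = 0.999 for each). None of these passed the test. Of 208 genes tested with edgeR, 0 were called at 24 h and 0 at 48 h. At an unadjusted p under 0.05, edgeR gave 0 genes at 24 h and 7 at 48 h (5 higher, 2 lower). DESeq2 called 0 genes at either time, with 1 and 7 genes under that unadjusted threshold. Chance gives 0.05 of the genes tested, and each of these unadjusted counts was below that share. Groups did not overlap for 17 genes at 24 h (8.17%, where chance gives 10%) and for 33 at 48 h (15.9%, where chance gives 20%). The median 95% half-width of a log2 difference was 0.80 at 24 h and 0.91 at 48 h, and the interval lay within 4-fold in either direction for 197 genes and for 180 genes.

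In 5637, the small Cajal body RNA SCARNA9 (chromosome 11, 93721513 to 93721865) came closest to a difference after HOXB13 siRNA. At 24 h it had 8 to 10 reads in the 3 libraries labelled HOXB13 siRNA and 0 to 1 in the 2 controls, 906 ± 280 against 53.9 ± 76.2 CPM (SD), a log2 difference of 3.75 ± 0.86 (95% interval 2.20 to 5.92, adjusted p = 0.107, edgeR). The osmotic stress transcription factor NFAT5 and the polyadenylation cleavage factor subunit CPSF6 differed by -2.02 ± 0.61 and -1.28 ± 0.41 at 24 h (adjusted p = 0.652 for both). At 72 h the small membrane protein gene SMIM15 differed by -1.58 ± 0.52, the chondroitin sulfotransferase CHST11 by 0.83 ± 0.28 and the SNARE protein SNAP29 by 0.97 ± 0.36, with the libraries of the groups apart for each (adjusted p = 0.990 for each). CPSF6, NFAT5, SMIM15 and SNAP29 overlap annotated genes on the opposite strand. Of 250 genes tested with edgeR, 0 were called at 24 h and 0 at 72 h. At an unadjusted p under 0.05, edgeR gave 11 genes at 24 h (6 higher, 5 lower) and 7 at 72 h (3 higher, 4 lower). DESeq2 called 0 genes at either time, with 4 and 1 genes under that threshold. Each of these unadjusted counts was below 0.05 of the genes tested, the share that chance gives. Groups did not overlap for 36 genes at 24 h (14.4%) and for 58 at 72 h (23.2%), where chance gives 20%. SCARNA9 shares its reference position with 2 small RNA entries on the same strand and passed the threshold with a filter at 1 CPM in 3 libraries (adjusted p = 0.0284), so its reads and its call are uncertain. Without the 24 h control replicate 3, edgeR called 1 gene at 24 h, the read-through gene BUB1B-PAK6 (adjusted p = 0.00299), which shares exons with BUB1B and PAK6 and was named after its value was seen. That sets 3 libraries against 1, with the spread taken from other groups, and is no support for a difference.

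In TCCSUP, the 3 genes with the smallest p after HOXB13 siRNA at 48 h were the cancer-testis gene SSX2, with a log2 difference of -0.74 ± 0.31, the cohesin acetyltransferase ESCO2, with -0.96 ± 0.44, and the GPI transamidase subunit PIGS, with 0.42 ± 0.19 (adjusted p = 0.986 for each, edgeR). SSX2 has a near-identical paralogue and SET has pseudogenes, so their reads may be divided between copies. At 72 h the histone chaperone SET had 2 to 5 reads in the 2 libraries labelled HOXB13 siRNA and 9 to 12 in the 3 controls, a log2 difference of -1.61 ± 0.55. The copper importer SLC31A1 differed by 0.65 ± 0.24 and the cyclophilin-related gene NKTR by -0.77 ± 0.30 (adjusted p = 0.992 for each of the 3 genes), and NKTR overlaps annotated genes on the opposite strand. Of 220 genes tested with edgeR, 0 were called at 48 h and 0 at 72 h. At an unadjusted p under 0.05, edgeR gave 3 genes at 48 h (1 higher, 2 lower) and 4 at 72 h (2 higher, 2 lower). DESeq2 called 0 genes at either time, with 0 and 1 genes under that threshold. Each of these unadjusted counts was below 0.05 of the genes tested, the share that chance gives. Groups did not overlap for 19 genes at 48 h (8.64%, where chance gives 10%) and for 30 at 72 h (13.6%, where chance gives 20%).

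**Figure D3:**
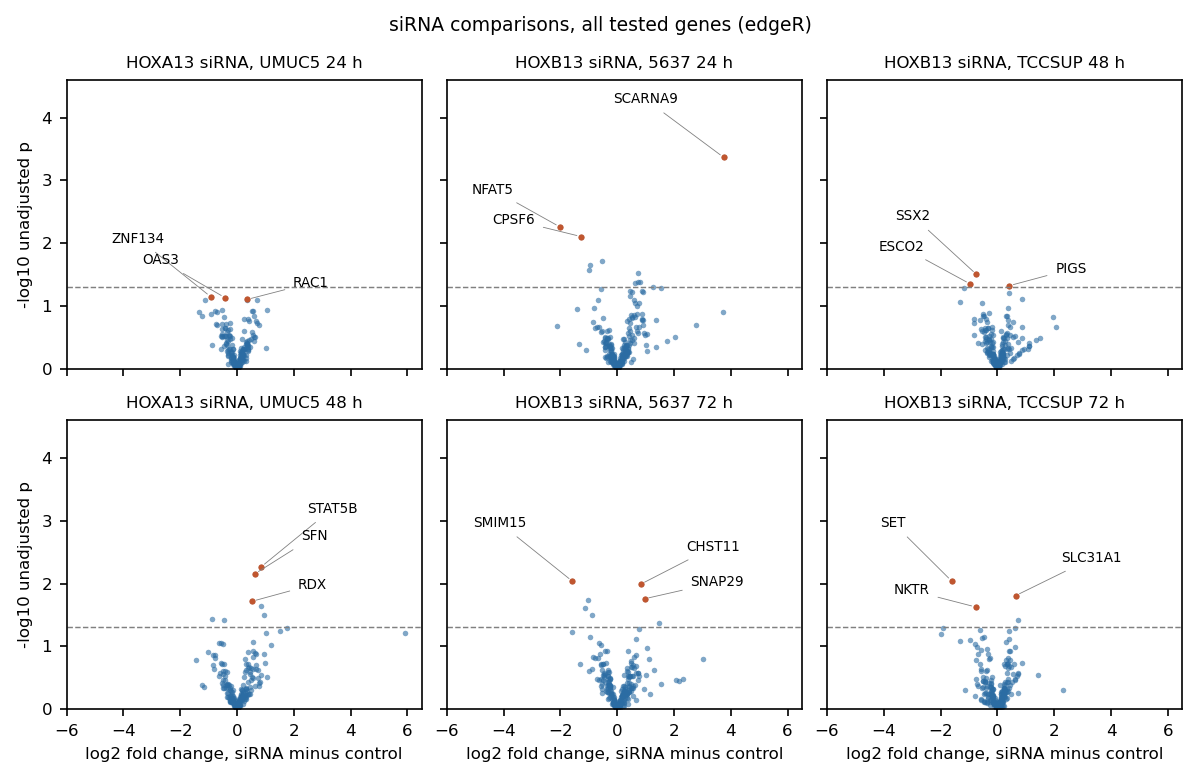
Log2 fold change of each tested gene, siRNA minus control libraries, on the x axis against -log10 of the unadjusted edgeR p on the y axis, 1 panel per cell line and time; each point is 1 gene, the 3 genes with the smallest p are coloured and named, and the dashed line marks the unadjusted threshold of 0.05. After adjustment 0 genes passed in any of the 6 panels, with SCARNA9 in 5637 at 24 h the closest (adjusted p = 0.107).

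What the 0 calls leave open differs between cell lines. In simulated libraries with known changes, edgeR recovered 2-fold changes for 37.1% of changed genes in the UMUC5 24 h comparison and for 32.9% at 48 h (208 genes), for 20% and 17.1% in 5637 at 24 and 72 h (250 genes), and for 30% at both times in TCCSUP (220 genes). For 4-fold changes the shares were 78.6% and 81.4% in UMUC5, 65.7% and 62.9% in 5637, and 74.3% and 74.3% in TCCSUP. Most single genes with a change near 2-fold would therefore have been missed, and these shares cover only genes that passed the filter of the main test. Each simulation changed 20 genes at once and drew genes independently of each other. A gene changed alone faces a stricter adjusted threshold, so its recovery would be below these shares.

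Whether the siRNA effect differed between collection times or cell lines was tested as an interaction in edgeR. STAT5B and SFN in UMUC5 had log2 differences of 1.04 ± 0.34 and 0.81 ± 0.27 between the 48 h and 24 h effects, and ARHGAP12, a gene of cell adhesion, had 2.10 ± 0.90, with adjusted p of 0.847, 0.847 and 0.981. In 5637 SCARNA9 had -3.74 ± 0.99 between the 72 h and 24 h effects (adjusted p = 0.355), NFAT5 1.94 ± 0.84 and SNAP29 1.06 ± 0.48. In TCCSUP the values were 1.34 ± 0.47 for SSX2, 1.08 ± 0.40 for the glycan-branching enzyme MGAT5 and -1.78 ± 0.68 for SET (adjusted p = 0.988 for each). edgeR called 0 genes in UMUC5, 0 in 5637 and 0 in TCCSUP, with 8, 3 and 5 genes at an unadjusted p under 0.05, and DESeq2 called 0 in each, with 4, 3 and 0. Leaving out the 24 h control replicate 3 gave 1 call in 5637, BUB1B-PAK6 again (adjusted p = 0.0109), also with 1 library in that group and the spread taken from others. Between TCCSUP and 5637 at 72 h, the HOXB13 siRNA effects differed most by p for SMIM15 (2.03 ± 0.73), the heterochromatin protein CBX3 (2.02 ± 0.76) and SET (-2.14 ± 0.81). edgeR called 0 of 268 genes there, with 10 at an unadjusted p under 0.05, and DESeq2 called 0, with 1. The unadjusted counts for these differences were each below 0.05 of the genes tested, the share that chance gives.

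The responses were also set side by side between lines collected at the same time, which share no libraries. Genes called in both lines numbered 0 in each of the 3 pairs, with 0 expected. Since each comparison called 0 genes, both numbers were fixed at 0 and say nothing about shared responses. The pairs with UMUC5 set HOXA13 siRNA against HOXB13 siRNA. Across the 168 genes tested in both UMUC5 and 5637 at 24 h, Pearson's r of the log2 differences was 0.12 and Spearman's correlation 0.19, and 57.7% of genes had the same sign. For UMUC5 and TCCSUP at 48 h the values were 0.09 and 0.09 across 141 genes, and for 5637 and TCCSUP at 72 h 0.03 and 0.13 across 158 genes. Between the times of 1 line they were -0.23 and -0.09 in UMUC5, 0.30 and 0.24 in 5637, and 0.05 and -0.01 in TCCSUP. These correlations are across genes, which are not independent replicates, and carry no p.

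Of the gene lists, those with at least 3 tested members were transforming growth factor beta and bone morphogenetic protein (TGF-beta and BMP) targets in 5637, the type I interferon response in TCCSUP and mitochondrially encoded mRNAs in both lines; UMUC5 had none. After HOXB13 siRNA in 5637, the TGF-beta and BMP targets CDKN2B, FST and INHBA had a median log2 difference of 0.12 at 24 h and -0.05 at 72 h (camera adjusted p = 0.728 and 0.936, limma). In TCCSUP, the interferon-response genes IFI44L, OAS3 and SAMD9L had medians of -0.17 at 48 h and -0.04 at 72 h (camera adjusted p = 0.251 and 0.529, limma). The number of list members called in the siRNA comparisons was 0 with edgeR, both over all genes and adjusted over the list alone. The mitochondrial list, fixed as a marker of RNA quality, was higher than other genes in TCCSUP libraries labelled HOXB13 siRNA at 48 h (8 members, median log2 difference 0.92, camera adjusted p = 0.00749 in limma). This call was lost with an estimated correlation (camera adjusted p = 0.300), and fry, which asks whether the members move 1 way, gave an adjusted p of 0.50. MT-ND5, a subunit of respiratory complex I, had a log2 difference of 1.95 ± 1.29, MT-CO3 of complex IV 1.36 ± 1.38, MT-ATP6 of the ATP synthase 1.10 ± 1.39 and MT-ND2 1.07 ± 1.52, none past the test. At 72 h in TCCSUP the list had a median of -0.42 (camera adjusted p = 0.529, limma).

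Mitochondrial reads varied widely between libraries of 1 group. In TCCSUP the 5 libraries with over 2000 genes detected (replicate 2 of each group and HOXB13 siRNA replicate 3 at 48 h) held at least 113 mitochondrial reads each and the other 6 at most 35. TCCSUP libraries labelled HOXB13 siRNA at 48 h held 78.2 ± 62.8 mitochondrial mRNA reads per 10000 reads on annotated genes (SD, n = 3; 12.3 to 137), and their controls 45.9 ± 54.3 (n = 3; 12.3 to 109). At 72 h the means were 60.6 ± 77.4 (n = 2) and 65.0 ± 71.9 (n = 3). In 5637 they were 85.5 ± 131 (n = 3) against 36.6 ± 46.5 (n = 2) at 24 h, and 71.1 ± 57.7 (n = 3) against 17.4 ± 2.37 (n = 2) at 72 h. The mitochondrial list in 5637 had a median log2 difference of 1.74 at 24 h (camera adjusted p = 0.558) and 2.18 at 72 h (camera adjusted p = 0.0581; adjusted p = 0.684 with an estimated correlation). In UMUC5 no group exceeded 2.38 such reads per 10000.

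Cells treated with control siRNA were compared between collection times, which shows how far the reads of a gene differed between these libraries without a HOX siRNA. Whether reads of a gene with a CA or TG run follow its expression over time was not tested. Differences between the libraries of 2 times may also be technical. In UMUC5, SFN fell from 71821 ± 7638 CPM at 24 h (SD, n = 3) to 28802 ± 3508 at 48 h (n = 2), a log2 difference of -1.31 ± 0.21 (SE; adjusted p = 0.00197, edgeR). The prostaglandin E synthase PTGES (chromosome 9, 129738331 to 129753047) fell from 29579 ± 3418 to 14883 ± 1012, a log2 difference of -0.99 ± 0.20 (adjusted p = 0.0156). These were the 2 genes called of 208 (0 higher, 2 lower; 31 at an unadjusted p under 0.05), and DESeq2 called 3. Both were lower in each 48 h control than in each 24 h control. Without the 48 h control replicate 3, which leaves 1 library at 48 h, edgeR called 0 genes, and 1 without the 48 h control replicate 2 or the 24 h control replicate 1 or 2. The 48 h controls also enter the SFN estimate for HOXA13 siRNA at 48 h, so the SFN values of these comparisons are not independent. Non-overlapping groups were counted for 70 genes (33.7%, where chance gives 20%).

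In 5637 controls, the annexin ANXA1 (chromosome 9, 73151757 to 73170393), a phospholipid-binding protein, rose from 1810 ± 29.9 CPM at 24 h to 6965 ± 1066 at 72 h (SD, n = 2 each), a log2 difference of 1.94 ± 0.32 (adjusted p = 0.00633, edgeR). The actin-associated gene SYNPO (chromosome 5, 150601080 to 150659220) rose by 1.91 ± 0.36 (adjusted p = 0.00852), and SCARNA9 by 5.24 ± 0.80 (95% interval 3.83 to 7.30, adjusted p = 0.00311) from the same 24 h controls that enter its siRNA estimate. Cyclin D1, CCND1, which drives entry into S phase (chromosome 11, 69641087 to 69654474), went from 3461 ± 132 to 746 ± 158 CPM, a log2 difference of -2.18 ± 0.38 (adjusted p = 0.00661). BCAR3, an adaptor of integrin signalling (chromosome 1, 93561786 to 93847150), and the membrane ubiquitin ligase gene MARCH4 (chromosome 2, 216257865 to 216372027) differed by -1.52 ± 0.32 and -1.45 ± 0.35 (adjusted p = 0.0192 and 0.0365). CCND1, BCAR3 and MARCH4 overlap annotated genes on the opposite strand, and the strand setting of the read counting is not given. In all, 9 of 250 genes were called, 6 higher and 3 lower at 72 h (39 at an unadjusted p under 0.05). DESeq2 called 0 (19 at an unadjusted p under 0.05), and edgeR called 1 to 2 when any of the 4 control libraries was left out, which leaves 1 library at that time. The groups did not overlap for 149 genes (59.6%, where chance gives 33.3%). Of the 3 TGF-beta and BMP targets 1 was called, also when adjusted over the list alone, and the list as a set was not (camera adjusted p = 0.766, limma), nor was the mitochondrial list (camera adjusted p = 0.766).

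In TCCSUP controls, SLC1A5 (chromosome 19, 46774883 to 46788594) rose from 41269 ± 6527 CPM at 48 h to 81091 ± 3744 at 72 h (SD, n = 3 each), a log2 difference of 0.97 ± 0.15 (adjusted p = 0.00352, edgeR). The cyclin-dependent kinase inhibitor CDKN2B (chromosome 9, 22002903 to 22009363) rose from 9506 ± 143 to 16658 ± 1567, a log2 difference of 0.81 ± 0.15 (adjusted p = 0.00676), and FAM167A (chromosome 8, 11421463 to 11475908) rose by 1.80 ± 0.40 (adjusted p = 0.0247). MGAT5 (chromosome 2, 134119983 to 134454621) went from 3254 ± 765 to 1085 ± 230, a log2 difference of -1.57 ± 0.27 (adjusted p = 0.00515). These were the 4 genes called of 220, 3 higher and 1 lower (21 at an unadjusted p under 0.05), with 3 higher and 3 lower when counts were scaled by library size only. DESeq2 called 1 gene, and edgeR called 7 without the 48 h control replicate 2. Groups were apart for 45 genes (20.5%, where chance gives 10%). Of the interferon-response genes 0 were called over all genes tested with edgeR and 1 was lower when adjusted over the list alone (camera adjusted p = 0.434, limma), and the mitochondrial list was not called (camera adjusted p = 0.434). The genes named as called with time in UMUC5, 5637 and TCCSUP carry a CA or TG run of 25 to 48 nt.

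**Figure D4:**
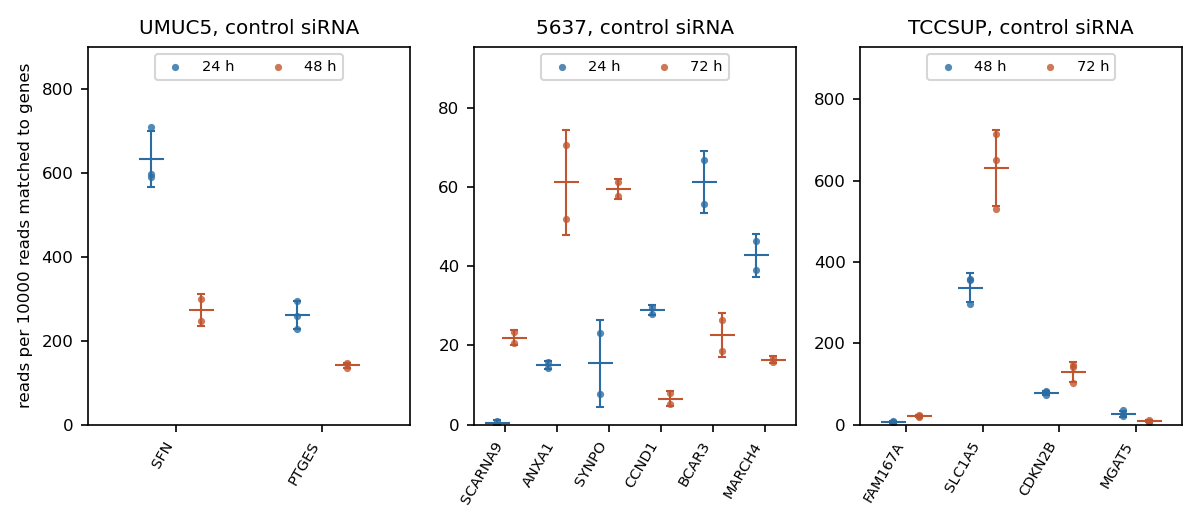
Reads per 10000 reads on annotated genes on the y axis for the genes named as called with time in cells given control siRNA, 1 panel per cell line; points are libraries, horizontal bars are means and error bars are 1 SD. SFN in UMUC5 is lower at 48 h than at 24 h in each library, and SLC1A5 in TCCSUP is higher at 72 h than at 48 h in each library.

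HOX genes as a family were near the floor in the control libraries. In UMUC5 controls 5 of the 38 HOX genes matched had a read, 20 reads in all, led by HOXD10 with 7 (127 ± 139 RPM, SD, n = 5). In 5637 controls HOXA3, HOXB7 and HOXD10 had reads, 33 in all, and HOXD10, a posterior HOXD gene, held 19 of them, 4 at 24 h (186 ± 263 RPM, SD, n = 2) and 15 at 72 h (762 ± 30.8 RPM, n = 2). HOXA3 had 5 at 24 h (216 ± 174 RPM) and 6 at 72 h (302 ± 128 RPM). TCCSUP controls had reads on 11 HOX genes, 27 in all, led by HOXC8 with 6 (87.7 ± 112 RPM, n = 6). With both times pooled, HOXD10 made up 58.7% of HOX RPM in 5637, and 35.3% of HOX TPM, transcript numbers that also divide by transcript length. By TPM, HOXB7 had the highest mean of the HOX genes in each of the 6 control groups, for example 69.3 ± 98.0 (SD) in 5637 at 24 h, where HOXD10 had 35.9 ± 50.8, and 176 ± 54.5 at 72 h, where HOXD10 had 166 ± 13.5. By RPM it shared the highest mean with HOXA3 in UMUC5 at 48 h (213 ± 86.3 for both), so which HOX gene leads depends on the unit and the group. Since reads were spread unevenly over transcripts in these libraries, these orders and shares describe the reads and do not rank the expression of the HOX genes.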

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

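The 3 tests in this part, the permutation test and both binomial tests, were chosen after the result was seen, and what would count against the binomial explanations was tightened after their values were known.

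HOXB13, which was not among the genes tested, had 10 reads in 5637, all in the 6 libraries labelled HOXB13 siRNA, and 0 in the 4 control libraries. It stands out because reads of a gene outside the tests were found where the controls held 0, and because their direction runs against the labels; but the siRNA libraries together held 142.9 reads per 1000000 reads on annotated genes (RPM), above 3 reads over all 4 controls pooled (71.0) and below 3 reads in each control library (266 at 24 h and 306 at 72 h), so the floor does not settle whether the controls were lower. Chance among libraries is not excluded: the exact two-sided permutation test of RPM gave p = 0.1333. This test could not decide. Only 4 libraries of 5637 held HOXB13 reads, all labelled HOXB13 siRNA, so the real arrangement was already the most extreme in its direction. The test could therefore not have given p under 0.05 for this pattern. Depth and a wider range of detected genes remain undecided. With the 10 reads spread by reads on annotated genes (37.6% in controls) the exact binomial chance of 0 in controls was 0.0089. Spread by genes detected (34.2% in controls) it was 0.0151. However, reads of 1 library can be copies of 1 molecule, and the test over libraries could not decide. An effect of the siRNA and an exchange of labels stay open at these counts and were not tested further.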

How the results depend on the processing

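Tests on genes without a CA or TG run, tests without the 6 libraries with over 2000 genes detected, tests with unmatched transcripts kept, and each alternative for the control comparisons between lines were chosen after the data were seen.

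For the 6 siRNA effects and the 4 differences of such effects, edgeR called 0 genes, and of 187 alternative values 183 were also 0, with 7 of the 10 results at 0 throughout. The highest value was 1. It was 1 in 5637 at 24 h with a filter at 1 CPM in 3 libraries (SCARNA9), and leaving out each library in turn gave 0 to 1 both there and for the difference between times in 5637, with BUB1B-PAK6, named after its value was seen, called without the 24 h control replicate 3, with 1 control library left at 24 h. The cause was not tested.

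Counts of genes changed with time in controls depended more on the setting. In UMUC5 the 2 calls became 4 with the filter at 1 CPM and 7 with only the compared groups in the fit, which included both called genes. In 5637 the 9 calls became 5 without a filter, 0 with DESeq2 and 26 with only the compared groups, which included all 9. In TCCSUP the 4 calls became 7 with RLE scaling, 2 without a filter, 1 with DESeq2, 9 with only the compared groups, which included all 4, and 9 without libraries with over 2000 genes detected. Restricting the test to genes without a CA or TG run gave 0 in each of these 3 results, where fewer genes enter and the genes named as called carry a run. Leaving out each library in turn gave 0 to 2 in UMUC5 (0 without the 48 h control replicate 3, which leaves 1 library, 1 without the 48 h control replicate 2 or the 24 h control replicate 1 or 2, and 2 without the 24 h control replicate 3), 1 to 2 in 5637, where each leaves a group of 1, and 3 to 7 in TCCSUP (7 without the 48 h control replicate 2). For control cells of different lines, DESeq2 called 71 for 5637 against UMUC5 and 81 for TCCSUP against 5637. Genes without a run gave 27 for 5637 against UMUC5, 21 for TCCSUP against UMUC5 and 38 for TCCSUP against 5637, with fewer genes tested, and leaving out each library gave 86 to 151 for TCCSUP against 5637. Apart from the fewer genes tested, the cause was not tested.

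Of the gene list tests, the 1 call in the siRNA comparisons, the mitochondrial list in TCCSUP at 48 h, became 0 with an estimated correlation and 0 with fry. It became 0 without libraries with over 2000 genes detected, where the list could not be tested. Among single genes named in the text, 1172 of 1222 alternative values stayed on their side of the threshold in the same direction, 49 lost the call, 1 gained it and 0 changed sign. Settings in which a gene was not tested are left out of these values. The values also cover genes without a call, for which staying uncalled counts as unchanged. Their share is therefore no measure of how stable the calls are. With counts scaled by library size only, the median log2 difference of all tested genes moved from 0.00 to -0.10 in UMUC5 at 48 h, from 0.04 to -0.08 in 5637 at 24 h, from 0.04 to -0.07 and from -0.12 to 0.01 for the difference between times in UMUC5 and 5637, and from 0.00 to 0.15 in UMUC5 controls with time.

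The replicate numbers were not taken to pair the libraries. Of 14 pairs of libraries with the same number, cell line and time, 9 had deviations from their group means that correlated above 0.1. Correlations ran from -0.48 to 0.73, and not each library correlated best with its own number. The labels' replicate entry contradicts the numbers used for controls of UMUC5 at 48 h and of 5637. In 5637 at 24 h same-number pairs correlated at -0.39 and -0.33, against means of 0.29 and 0.19 with other numbers. For those controls the check cannot decide on pairing, and the block uses the same numbers. In a group of 2 libraries the deviations mirror each other, so pairs there, also those of TCCSUP at 72 h, are not independent. Both TCCSUP pairs at 72 h correlated (0.73 and 0.57), and 5 of the 6 libraries with over 2000 genes detected carry number 2. With the replicate number as a block, calls with time in controls became 1 in UMUC5, 3 in 5637 and 6 in TCCSUP, the 72 h difference between lines became 1 (MT-CO1, named after its value was seen), and the mitochondrial list stayed called in TCCSUP at 48 h (camera adjusted p = 0.000211 with the preset correlation, which without a block was lost with an estimated one). The other counts of siRNA effects stayed at 0 under the block.

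In UMUC5 at 24 h and in TCCSUP at 48 h and in TCCSUP controls with time, 3 libraries face 3, and the 10 splits of 6 libraries are too few for a share under 0.05. The real split and the highest other split called 0 and 0 genes in UMUC5 at 24 h, 0 and 0 in TCCSUP at 48 h, and 4 and 1 in TCCSUP controls. Depth limits all of these results: only 208 to 250 genes per line passed the filter of the main test.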

Other observations

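The comparison of control cells between lines, the tests of opposite-strand overlap and of sequencing run were chosen after the data or the result were seen, as was the spread set against the test of reads divided between genes.

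Control siRNA cells of the 3 lines differed from each other in the reads of many of the genes tested. Genes with a CA or TG run of at least 20 nt were 67.0% of those tested for 5637 against UMUC5. The shares were 72.1% for TCCSUP against UMUC5 and 71.9% for TCCSUP against 5637. Of the genes named for these comparisons, FST, SOX4, RAC1, ASCC2, ITGA11, COL1A1 and IFI44L had no such run. The others had 1 of 23 to 60 nt. Whether reads of a gene with a run follow its expression in each line was not tested. At 24 h, 5637 controls stood above UMUC5 controls in INHBA, the activin A subunit, at least 66.7-fold, in the Wnt ligand WNT7A at least 47.8-fold, in MARCH4 at least 15.9-fold, in the ceramide galactosyltransferase UGT8 at least 13.6-fold, in the kinase SBK1 at least 11.7-fold and in CDKN2B at least 7.75-fold. Each had 0 reads in UMUC5, and the bounds set mean RPM, without TMM scaling, against 3 reads per library. The activin antagonist FST was higher by 2.22 ± 0.51 on the log2 scale, so all 3 tested TGF-beta and BMP targets were called higher, also when adjusted over the list alone (camera adjusted p = 0.00347 in limma; 0.123 with an estimated correlation). CPA4, the transcription factor SOX4 and BCAR3 were higher by 3.40 ± 0.26, 3.46 ± 0.28 and 4.596 ± 0.415. In the other direction, 5637 had 0 reads of RDX, OAS3 and the helicase cofactor ASCC2, at least 33.3-fold, 26.8-fold and 4.85-fold lower than UMUC5. The RNA-granule protein LSM14A, with 0 to 1 reads in 5637, differed by -6.22 (95% interval -7.86 to -5.23), PTGES by -5.04 ± 0.25, RAC1 by -3.36 ± 0.30 and the collagen prolyl hydroxylase P3H2 by -3.48 ± 0.33. edgeR called 128 of 221 genes, 70 higher and 58 lower in 5637, and DESeq2 called 71. Mitochondrial reads, the marker of RNA quality, also differed between these groups. They were 36.6 ± 46.5 per 10000 (SD, n = 2) in 5637 controls and 0.601 ± 0.526 (n = 3) in UMUC5 controls. Whether this bears on the genes called was not tested. With counts scaled by library size only, the median of all genes moved from 0.17 to 0.37.

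TCCSUP controls stood apart from both other lines in BGN, CPA4 and SFN. The fold bounds are again in RPM, without TMM scaling, and leave out the spread of the group with reads. At 72 h BGN in TCCSUP was 14285.5 CPM, TMM-scaled, and 9771.2 RPM, while WNT7A in 5637 was 10274.5 CPM and 10052 RPM. On the scale of the log2 differences, bounds for genes lower in TCCSUP would therefore be smaller. Against UMUC5 at 48 h, the antisense RNA MSC-AS1 was at least 31.96-fold higher, the proteoglycan BGN at least 22.6-fold, CDKN2B at least 21.4-fold, the mucin MUC15 at least 10.2-fold and the integrin ITGA11 at least 9.07-fold. CPA4 was higher by 7.65 ± 0.37 and COL1A1, a fibrillar collagen chain, by 5.97 ± 0.42 on the log2 scale. The ephrin EFNB1 was at least 58.0-fold lower, the flippase subunit TMEM30B at least 49.5-fold, the sorting nexin SNX2 at least 12.8-fold and the podosome scaffold SH3PXD2A at least 10.5-fold. PTGES differed by -6.15 ± 0.31, the endoplasmic reticulum protein REEP5 by -5.84 ± 0.33, the exchange factor RAPGEFL1 by -4.63 ± 0.34, and SFN, with 0 to 1 reads per library in TCCSUP, by -9.08 (95% interval -10.53 to -8.56). Of the interferon-response genes OAS3 was higher by 1.91 ± 0.21 and IFI44L at least 2.63-fold, and SAMD9L differed by -1.08 ± 0.28 (camera adjusted p = 0.377). Against 5637 at 72 h, BGN was at least 31.96-fold higher, MUC15 at least 12.6-fold, LSM14A at least 11.9-fold and the fatty acid receptor CD36 at least 11.8-fold. MSC-AS1 was higher by 8.45 ± 0.42, OAS3 by 7.73 ± 0.50, RDX by 7.002 ± 0.333 and CPA4 by 2.54 ± 0.16. WNT7A was at least 40.9-fold lower, TMEM30B at least 24.0-fold, UGT8 at least 23.2-fold and the acetyltransferase EP300 at least 18.4-fold. SFN differed by -7.57 ± 0.50 (95% interval -8.91 to -6.70), CBX3 by -5.92 ± 0.46, EFNB1 by -5.57 ± 0.48, RABGAP1 by -4.74 ± 0.38 and the focal adhesion gene TNS4 by -4.15 ± 0.32. MSC-AS1, MUC15, TMEM30B, REEP5, SOX4, EP300 and CBX3 overlap annotated genes on the opposite strand. OAS3 and IFI44L were called higher there and SAMD9L only when adjusted over the list alone (camera adjusted p = 0.0333; 0.141 with an estimated correlation). edgeR called 111 of 204 genes against UMUC5 (68 higher, 43 lower; DESeq2 86) and 142 of 231 against 5637 (74 higher, 68 lower; DESeq2 81). Scaled by library size only, the calls against 5637 were 48 higher and 100 lower and the median of all genes moved from -0.13 to -0.57, and against UMUC5 it moved from 0.18 to -0.04. The count against 5637 was 92 without its 72 h control replicate 1 and 86 without replicate 3, each with 1 library of 5637 left.

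Markers of other cell types were counted from lists written beforehand. Counts of 0 in these libraries do not show that such cells were absent, since GAPDH also had 0 reads in the UMUC5 libraries. Endothelial markers had 0 reads in each line and arm, with 8 markers matched, leukocyte markers at most 1 read, and smooth muscle markers at most 2 reads in UMUC5 and 5637 and, in TCCSUP, 5 reads in libraries labelled HOXB13 siRNA and 15 in their controls (0.79 and 2.09 per 10000), a difference not tested. Fibroblast markers held 71.0 reads per 10000 in TCCSUP libraries labelled HOXB13 siRNA and 68.6 in their controls, mostly COL1A1 (396 and 440 reads), against 3.00 and 1.42 in 5637.

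Reads concentrated on transcripts with long CA or TG runs: those with a run of at least 30 nt were 0.538% of protein-coding transcripts and held 56.76% of their reads. Transcript length is argued against, since among transcripts of 3000 to 5000 nt the reads per transcript with such a run were 153.5 times those of transcripts without a run of 10 nt. For opposite-strand counting, the share of overlapped genes among the 200 with most reads was 0.84 of that among those ranked below them to 1000. This argues against such counting between protein-coding genes as what put these 200 genes at the top. Overlaps with noncoding genes were not counted, and genes with and without a run were not compared. The test therefore leaves this explanation of the run pattern undecided. Reads divided between genes stay undecided: 9.1% of the reads of genes with a run of at least 20 nt lay in values that were not whole, under the bound of 10% set beforehand, but the share ranged from 3.11% to 21.32% over 57 runs, and whole values exclude only division into fractions. Capture or priming at such runs during library preparation is a candidate explanation that was not tested, and some other repeats show an excess too (57008.6 reads per 1000 transcripts for AG or CT runs of 30 nt without a CA or TG run of 10 nt, on 16 transcripts, 15823.9 for A or T alone, on 28, and only 3449.9 for AT, on 13, against 1978.3 without a CA or TG run of 10 nt, all of 3000 to 5000 nt), and the design gives no biological explanation to test.

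Libraries of 1 group differed in how many genes had a read, by a median ratio of 2.24 between the highest and lowest library over the 8 groups of 5637 and TCCSUP. Depth is argued against as the whole cause, since after thinning each library to 6584 reads on annotated genes the median ratio was 1.92, from 1.113 in 5637 controls at 72 h to 2.357 in 5637 HOXB13 siRNA libraries at 24 h. The sequencing run was tested by mitochondrial reads per 10000. These differed between runs of 1 library by 0.11 of what libraries of 1 group differed by (median absolute log2 ratio 0.30 over 17 run pairs and 2.65 over 18 library pairs). That argues against the run as the source of the mitochondrial differences. Genes detected were not compared between runs at equal depth, so the run is not excluded for them. An effect of HOXB13 siRNA remains undecided, with an exact two-sided permutation p of 0.5326 for genes detected within cell line and time. Differences in library preparation or RNA quality between replicates may remain and were not tested; of the 6 libraries with over 2000 genes detected 5 carry replicate number 2, among them that of each TCCSUP group.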
